A study of Nicotiana tabacum with 4 samples.

How the data were processed

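Messenger RNA of young primary leaves of tobacco, Nicotiana tabacum, was measured by RNA-seq in 4 libraries. They came from 2 samples of plants carrying Wov, an allele of the tomato Woolly gene, and 2 samples of wild-type (WT) plants. Woolly encodes a homeodomain-leucine zipper transcription factor of class IV that acts in the formation of multicellular trichomes. Per the labels' protocols, leaves were frozen, total RNA was extracted with TRIzol and libraries followed the standard Illumina procedure. TopHat, a spliced read aligner, is named in the submitters' processing notes. Its version, the counting program, the genome build, the gene models and the use of strand are not given in the sources used here. Nothing states whether the libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be partly technical.

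The authors deposited 1 table of read counts per gene model and 1 table of FPKM, both of 50705 gene models in the same 4 libraries. The counts were whole numbers, and their totals ran from 9126074 to 11736154 reads per library. Every deposited FPKM above 0, 181596 values in all, equalled the read count divided by a gene length and by the library's total in the count table, within a relative tolerance of 1e-04. The FPKM are therefore the counts on another scale and no independent measurement. The division gave a length for the 48127 models with at least 1 read, whole in each case within 0.05 bases, with a median of 2153 and a range from 98 to 114303 bases. No table column was left unused.

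Gene models carry only numbered IDs. None of the 50705 IDs (0) matched a gene ID, locus tag, symbol, synonym or RefSeq accession of the reference table for assembly ASM71507v2, and the deposited tables pair the IDs with no names. Gene lists fixed before the data were examined (cell division, trichome regulators, terpenoids, cuticle, hormones, photosynthesis, defence and markers of other leaf cell types, among others) could therefore not be matched, and none was tested. The rule fixed for named genes was the 10 largest changes in each direction at an adjusted p under 0.05 with a description, and at most 2 IDs per direction where IDs have no names. No gene passed that threshold, so the 2 IDs with the smallest p in each direction, among genes with at least 20 reads in each library of the higher group, were chosen after their values were seen.

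The comparison used edgeR 4.0.16 under R 4.3.3, with all 4 libraries, no covariate, the default filter on low counts (38981 models kept), TMM scaling and the robust quasi-likelihood test, two-sided. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Log2 CPM with a prior count of 2 served for correlations, principal components and counts of genes set apart. A gene was called set apart when both libraries of one group lay more than 4-fold above both of the other on that scale. This count has no p-value and was added after seeing that no gene passed the adjusted threshold. Standard errors of log2 fold changes were the fold change divided by the square root of its F statistic. Counting intervals of ratios and shares are exact 95% intervals and cover counting error only.

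The procedure was tested on simulated data. Counts for this comparison were drawn from the measured means, library sizes and dispersions, with 200 models changed, none of them of low mean abundance. At the measured dispersions, 28.4% of 67 models changed 4-fold were called, as were 100% of the 67 models changed 16-fold and 100% of the 66 changed 64-fold, among 38030 models in the test. Of the 176 calls, 24 were of unchanged models. The median prior degrees of freedom, which measure how alike the genes' spreads are, came to 22.3 in the simulation and 4.06 in the deposited counts. Spreads were thus more alike in the simulation, so its shares called may overstate the power in the deposited counts. There, no model was called, not even the 62 higher and 13 lower ones more than 16-fold apart in every pair of libraries across the genotypes.

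Alternatives planned before the data were examined were DESeq2 1.42.0, the edgeR exact test, a test against a 2-fold change, other scalings and filters, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), the 20 most abundant models left out, the replicate number as a block, and each library left out in turn.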

Results

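The leaf transcriptome of tobacco plants carrying the tomato Wov allele was compared with that of wild-type plants in 2 libraries per genotype. The Wov libraries held 9126074 and 10813356 reads, and the WT libraries 11736154 and 11110640 reads. Between 45257 and 45578 of the 50705 gene models had at least 1 read in a library, and 2578 had none in any. The most abundant model, gene_44833, held 120286 and 200604 reads in the Wov libraries and 166713 and 169969 in the WT libraries. The 20 most abundant models of a library together took from 5.38% of its reads in WT 1 (95% exact binomial interval 5.37 to 5.39) to 6.23% in Wov 2 (6.21 to 6.24). Reads of the introduced tomato gene were not analysed here, because the IDs are not paired with gene names. For the same reason no marker of a leaf cell type and no sign of RNA quality that rests on named genes was measured.

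The first question was how closely the libraries of a genotype resembled each other. The WT libraries were the closest of all 6 pairs, with a Pearson correlation of log2 CPM across genes of 0.92. The Wov libraries correlated at 0.88. Wov 2 correlated at 0.89 with WT 1 and at 0.87 with WT 2, so by this measure it lay about as near to the wild type as to the other Wov library. Wov 1 was farthest from the wild type, at 0.77 with WT 1 and 0.84 with WT 2. These correlations are across genes, which are not independent replicates. At least a 2-fold difference separated Wov 1 from Wov 2 in 10026 of the 38981 tested models, against 4892 models between the WT libraries. Wov 2 differed by as much from WT 1 in 8010 models and from WT 2 in 8375, fewer than from Wov 1, while Wov 1 differed from WT 1 in 15197 and from WT 2 in 11569. Wov 1 alone lay more than 4-fold below all other libraries in 459 models and more than 4-fold above them in 146. The corresponding numbers for Wov 2 were 124 and 11. No library was another one sequenced again or deposited a second time: a chi-square of their counts per degree of freedom ran from 23.3 for the WT libraries to 80.4 for Wov 1 and WT 1, where sampling noise alone gives a value near 1. Repeat preparations from one RNA are not excluded by this. Gene length correlated at 0.22 across genes with the log2 difference of Wov 1 minus Wov 2 and at -0.095 with that of WT 1 minus WT 2.

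The first principal component held 59.3% of the variance and placed both Wov libraries on one side, at scores of -147 and -24.6, and both WT libraries on the other, at 113 and 58.2. The second component held 29.8% and did not follow genotype. On it, Wov 1 (34.5) and WT 2 (87.4) lay opposite Wov 2 (-100.0) and WT 1 (-21.9).

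**Figure D1:**
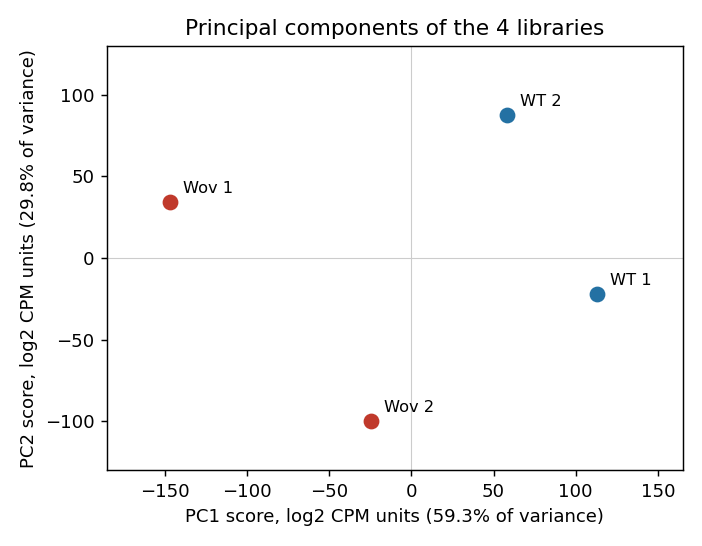
Scores of the 4 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; red points are Wov and blue points WT libraries. On the first axis Wov 1 lies at -147 and Wov 2 at -24.6, with WT 2 at 58.2 and WT 1 at 113. Along that axis alone, Wov 2 is nearer to WT 2 than to Wov 1. On the second axis Wov 2 (-100.0) is farther from WT 2 (87.4) than from Wov 1 (34.5). The second axis sets Wov 2 and WT 1 apart from Wov 1 and WT 2.

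The central comparison asked which transcripts differ in abundance between Wov and wild-type leaves. In both Wov libraries, 471 gene models were more than 4-fold above both WT libraries, and 116 were more than 4-fold below them. The excess of higher models shrank when a Wov library was left out, to 566 higher and 398 lower without Wov 1 and 1185 and 1139 without Wov 2. Without WT 1 the counts were 921 and 243, and without WT 2 they were 942 and 244. The higher set had a median abundance of 8.77 CPM in Wov and 0.574 CPM in WT, and its median log2 fold change was 3.93. In the lower set the medians were 0.638 CPM in Wov and 8.62 CPM in WT, with a median log2 fold change of -3.61. A gap of more than 16-fold in every pair of libraries was seen in 62 higher and 13 lower models. Of the 471 higher models, 46 exceeded 100 CPM in Wov, up to a mean of 1894 CPM. Of the 116 lower models, 6 exceeded 100 CPM in WT, up to 155 CPM. The higher set made up 2.41% of all reads in Wov 1 (95% exact binomial interval 2.40 to 2.42) and 1.97% in Wov 2 (1.96 to 1.98), against 0.165% in WT 1 (0.162 to 0.167) and 0.139% in WT 2 (0.137 to 0.141). The lower set made up 0.0210% and 0.0244% of the Wov libraries and 0.240% and 0.226% of the WT libraries. Both sets were picked on these libraries, so the shares describe them and are no separate evidence.

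These differences did not pass a threshold corrected for the number of genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 38981 models had an adjusted p under 0.05, and the smallest adjusted p was 0.0771. At an adjusted p under 0.1 there were 152 models, 120 higher and 32 lower in Wov. An unadjusted p under 0.05 was reached by 5560 models, 14.3% of those tested. If no gene differed, the average count would be 1949. Genes vary together, so the count of 1 comparison can lie far from that average, and the gap is no test. Of the 5560 models, 3134 were higher and 2426 lower in Wov, and 2786 and 2110 of them differed at least 2-fold. The 587 models set apart 4-fold all had an unadjusted p under 0.05, with adjusted p from 0.0771 to 0.274. DESeq2's Wald test on the same counts called 1392 models at an adjusted p under 0.05, 967 higher and 425 lower. The edgeR exact test called 1705, of which 1161 were higher and 544 lower. The DESeq2 calls included 521 of the 587 models set apart 4-fold, and the exact test's included 587. Leaving out Wov 1 gave 198 calls by the quasi-likelihood test and leaving out Wov 2 gave 2416, against 1 without WT 1 and 4 without WT 2, with the lone library assumed to vary like the others. A block that joins Wov 1 with WT 2 and Wov 2 with WT 1, an alternative chosen after seeing the data that no label supports, took the count from 0 to 5651. Because that block follows a deviation seen in these same libraries, it removes residual spread by selection, and the rise is no separate evidence. The share of higher models among those at an unadjusted p under 0.05 was 56.4% with all libraries but 46.5% without Wov 1, 46.8% without Wov 2 and 48.4% with all libraries under that block. It was 66.3% without WT 1, 62.8% without WT 2, 59.4% with the replicate number as a block and 67.8% in the test against 2-fold, so the direction of that majority depended on the libraries and the fit.

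**Figure D2:**
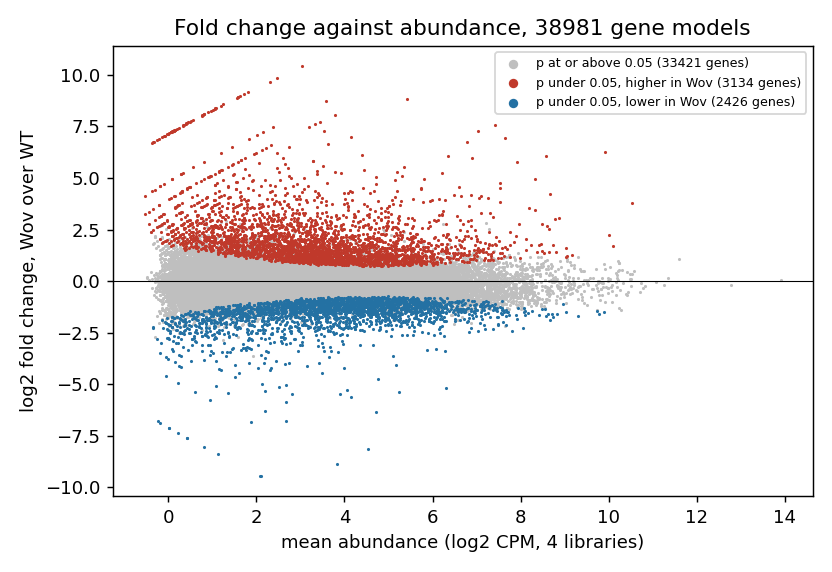
Fitted log2 fold change of Wov over WT (vertical axis) against mean abundance in log2 CPM (horizontal axis) for the 38981 tested gene models, each a point. Red points are the 3134 models higher and blue points the 2426 lower in Wov at an unadjusted p under 0.05, and none passed an adjusted p of 0.05.

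The 2 IDs with the smallest p in each direction were chosen after their values were seen. Among higher models, gene_57928 stood at 79.3 ± 20.02 CPM (SD, n = 2) in Wov and 1.70 ± 0.196 CPM in WT, from 864 and 717 reads against 21 and 17. Its log2 fold change was 5.54 (SE 0.42), a ratio of 45.9 with a counting interval of 33.3 to 65.2. The model gene_16993 stood at 161 ± 34.2 CPM in Wov and 2.38 ± 0.396 CPM in WT (SD, n = 2), a log2 fold change of 6.08 (SE 0.46) and a ratio of 67.1 (51.2 to 89.8). Among lower models, gene_80083 had 2 and 1 reads in the Wov libraries and 650 and 381 in the WT libraries. The WT level was 311 times that of Wov, with a counting interval of 106 to 1512. The model gene_15167 had 2 reads in each Wov library and 150 and 121 in the WT libraries, a WT level 61.4 times that of Wov (23.7 to 227). All 4 had an adjusted p of 0.0771 in edgeR's quasi-likelihood test, and each kept its direction in all 18 alternative fits. Gaps this wide between the groups left little room for a reversal, so the kept direction is no separate support. The call itself depended on the fit: gene_80083 passed an adjusted p of 0.05 in 10 of the 18 and each of the others in 8, and the highest adjusted p of each was 0.18. Lengths behind the FPKM were 992 bases for gene_57928, 4480 for gene_16993, 1282 for gene_80083 and 1377 for gene_15167.

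Presence against absence gave a smaller set. There were 19 models with at least 20 reads in both Wov libraries and no read in either WT library, and 5 with the reverse pattern. The split of Wov 1 and WT 2 against Wov 2 and WT 1 gave 0 and 5 such models, and the split by library number 0 and 0, so the 5 absent in Wov were matched by a split that does not follow genotype. A count of 0 in a library allows up to 3 reads at this depth, so these models are not shown to be silent in the lower group.

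The other splits of the 4 libraries were counted in the same way. They give no chance level, because any genotype difference lies within their groups and widens the spread there. Pairing each Wov library with the WT library of its own number set 1 model apart 4-fold in total and gave 40 models at an unadjusted p under 0.05. Pairing Wov 1 with WT 2 and Wov 2 with WT 1 set 227 models apart and gave 2022. The labelled split gave 587 and 5560. Groups that did not overlap at all were found in 49.1% of models under the labelled split, where chance gives 33.3% on average. Under the others they were found in 15.6% and 35.3%. A model without ties is separated in only 1 of the 3 splits, so a high share in the labelled split lowers the others. With 3 possible splits, no permutation of the labels can give a p below 0.333.

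**Figure D3:**
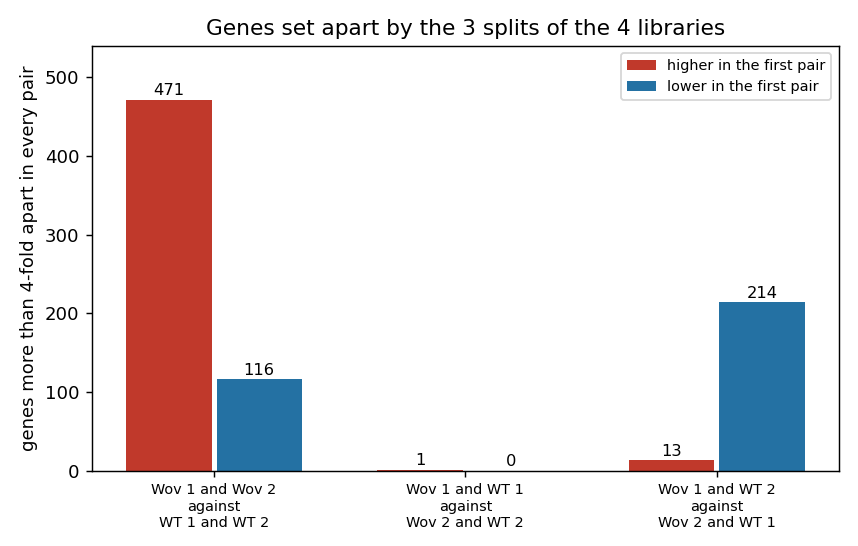
Number of gene models (vertical axis) with every library of the first pair more than 4-fold above (red) or below (blue) every library of the second pair, for the 3 ways to split the 4 libraries. The labelled split gives 471 and 116, the split by library number 1 and 0, and the crossed split 13 and 214.

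The models at an unadjusted p under 0.05 were spread over all abundances and lengths. In the most abundant 20% of models, 8.30% were higher and 8.88% lower in Wov at an unadjusted p under 0.05. In the least abundant 20%, 7.25% were higher and 4.07% lower, and the higher share ran from 7.18% to 8.95% over the 5 abundance classes with no steady order. The lower share was larger in each more abundant class, from 4.07% through 4.39%, 6.05% and 7.73% to 8.88%. Among the longest 20%, from 4434 bases, 5.91% were higher and 5.46% lower, and among the shortest 20%, from 98 to 1213 bases, 8.09% and 5.87%. The 3 classes between them had 8.34% to 9.24% higher and 6.45% to 6.79% lower. The median log2 fold change over all tested models was -0.01. In the most abundant 20% it was -0.093, and in the other abundance classes it ran from -0.006 to 0.021. These shares and medians describe genes within 1 comparison and were not tested against each other.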

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

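The number of genes past an adjusted p of 0.05 was 0 under each other scaling of the edgeR fit but moved with the test and the filter. It was 0 in 8 alternatives, among them DESeq2 size factors, upper quartile scaling, library totals, a stricter count filter, the test against 2-fold and the fit without the 20 most abundant models. It was 178 with no count filter, 1392 with DESeq2, 1705 with the edgeR exact test, 108 with limma on log2(FPKM + 1) and 21 on log2(FPKM + 0.1). DESeq2 (48127 models fitted, 41614 of them given an adjusted p) and limma (32541 models) differed from the edgeR fit in filter as well as test. Dropping the filter took limma on log2(FPKM + 1) from 108 calls to 0, whereas it took edgeR from 0 to 178. All calls of the filtered limma fits and of the unfiltered edgeR fit lay among the models set apart 4-fold. The cause of these differences was not tested. The number at an unadjusted p under 0.05 fell from 5560 to 2152 in the test against 2-fold, which asks for more by construction. The 4-fold counts, 471 higher and 116 lower, became 177 and 46 on log2(FPKM + 1) with and without the filter, where a pseudocount of 1 shrinks low values. Leaving out libraries in turn gave 1 to 2416 calls and 2725 to 10734 genes at an unadjusted p under 0.05. It gave 566 to 1185 models 4-fold higher and 243 to 1139 lower, since fewer libraries have to stand apart, and without Wov 2 the split was nearly even at 1185 and 1139. On log2(FPKM + 1) the correlation was higher than on log2 CPM for every pair of libraries. That of Wov 1 with WT 1 was 0.84. Wov 2 correlated at 0.921 with Wov 1, 0.919 with WT 2 and 0.933 with WT 1, the same order as on log2 CPM. With the replicate number as a block, 0 genes passed the adjusted threshold and 2921 an unadjusted p under 0.05. The deviations of libraries with the same number correlated at -0.49 across genes, so the numbers were not taken as pairs. With the crossed pairing as a block, chosen after seeing the deviations of these same libraries, 5651 genes passed the adjusted threshold, 2898 higher and 2753 lower. An unadjusted p under 0.05 was reached there by 10773, 5214 higher and 5559 lower. The majority of higher models at that p (3134 against 2426) thus turned there, as it did without Wov 1 (2279 against 2618) and without Wov 2 (5024 against 5710). The 4 named IDs, picked for their small p in these same libraries, kept their direction throughout. For gene_80083 the adjusted p ran from 2.8e-20 in the edgeR exact test to 0.18 with the replicate number as a block. The planned gene list tests were not run, because no ID could be paired with a name.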

Other observations

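In the paragraphs below, the tests of thinning, length trend and mixture were set before their results were seen, and those of the swap, the shared day, the splits and the neighbouring IDs were chosen after the pattern was seen. Some of the most abundant transcripts were uneven between libraries of one genotype. The model gene_61506 had 69599 reads in Wov 1 and 10119 in Wov 2, against 19808 and 24769 in WT 1 and WT 2. The model gene_72431 had 13176 and 45339 reads in the Wov libraries and 4418 and 150 in the WT libraries, and its adjusted p was 0.337 in edgeR's quasi-likelihood test. Both were singled out after their values were seen.

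Within each genotype the libraries differed along a partly shared direction. The difference of Wov 1 minus Wov 2 and that of WT 1 minus WT 2 correlated at -0.49 across genes. Unequal depth is argued against, since the correlation was -0.49 after every library was thinned to 9126074 reads. A trend with gene length is also argued against, with -0.49 after a smooth trend was removed. A swap of libraries between genotypes would make another split stronger than the labelled one, but the labelled split set 587 models apart and the highest other split 227. No label gives a day, a batch or a difference in leaf stage. A day or batch joining Wov 1 with WT 2 and Wov 2 with WT 1 could make this correlation negative. So could a natural difference such as leaf stage, and neither fixes its size, so the value of -0.49 cannot tell them apart.

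The Wov libraries differed from each other at least 2-fold in 2.05 times as many models as the WT libraries did. Unequal depth is argued against: after thinning the ratio was 1.98. A trend with gene length, which correlated at 0.22 with the Wov difference, is argued against as the whole cause by a ratio of 1.95 once a smooth trend was removed. Wild-type material mixed into Wov 2 is argued against by 39 models that had at least 50 reads in each WT library and were at least 32 times lower in Wov 1. Of these, 38.5% (95% exact binomial interval 23.4 to 55.4) lay under 5% of the WT level in Wov 2, below what a larger share of wild-type RNA would bring, although the median over the 39 was 18.8% and the upper quartile 49.98%. A smaller share of wild-type RNA, RNA or library quality in other respects, and a different strength of the transgene in the sampled plants stay open and were not tested.

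For the count of 5560 genes at an unadjusted p under 0.05, 1 of the 3 splits gave as many, the labelled one, and the highest other split gave 2022. The splits are too few for a share under 0.05, and the other splits hold any genotype difference within their groups.

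Models with adjacent ID numbers had related fold changes. Across 24671 neighbouring pairs the fold changes of Wov over WT correlated at 0.069, above the highest of 1000 shuffles of the IDs (0.022), and at -0.0039 for IDs 100 apart. Of these pairs, 60 had both members at an unadjusted p under 0.01 in the same direction, against a mean of 27.2 and at most 45 in shuffled IDs. Near copies of similar length that share reads do not account for the whole. Neighbours whose lengths differed more than 2-fold still correlated at 0.061 (95% interval 0.044 to 0.079), against 0.115 for 2667 pairs of like length. Pairs of genes are not independent replicates, so that interval does not measure the spread between samples. The relation was not particular to genotype: neighbours also correlated at 0.053 in the difference between Wov libraries and at 0.041 between WT libraries. It may reflect an ID order that follows the genome, with neighbouring genes or split gene models varying together, which was not tested; the 0.061 among unlike lengths leaves both open.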
